A study of Mus musculus with 27 samples.

How the data were processed

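The series holds 27 mouse samples. Of these, 16 are RNA-seq libraries of liver tissue taken 24 hours after surgery, and 11 are CUT&RUN samples of primary hepatocytes, in which an antibody directs DNA fragmentation to the sites that its target occupies. The livers came from wild-type mice (WT) and from mice that carry a floxed Acly gene and the Alb-cre transgene, which removes the floxed part in hepatocytes (KO). Each genotype had sham surgery or ischemia-reperfusion (IR) surgery, with 4 libraries per group. The hepatocytes were put into normoxia or hypoxia-reperfusion (HR) culture 24 hours after isolation. A peak list was used for 8 of the CUT&RUN samples: H3K27ac and H3K9ac, both marks of active chromatin, in WT normoxia, WT HR and KO HR, and an anti-FLAG antibody for ACLY in WT normoxia and WT HR. How the FLAG tag was brought into WT cells is not given in the sources used here. The 3 IgG control samples were not analysed here. Groups were taken from the sample titles.

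Per the submitters' processing notes, the tools used were Trimmomatic and kallisto and the genome build was mm10, with no versions. The RNA files hold, per the file headers, kallisto's length, effective length, estimated count and TPM for each of 111462 transcripts, as the authors deposited them. The estimated counts were rounded to whole numbers for testing, and the deposited TPM values were used only to describe levels. The deposited peak lists give for each peak a total signal and a maximum signal from the authors, on a scale whose normalization is not given in the sources used here. The aligner and the peak caller of the CUT&RUN data are likewise not given in the sources used here. Signal was therefore used only to rank peaks within a list and never compared across lists, except for 1 maximum that is described as a ratio. The WT lists have coordinates on a grid of 10 bp (99.98% to 100.0% of peaks) and the KO lists do not (0.94% and 1.01%), so the WT and KO lists were not made in the same way.

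The RNA files identify transcripts by Ensembl transcript identifiers without gene names, and no table pairing these identifiers with genes was used here. Counts were therefore tested per transcript and not summed per gene, no gene list was tested in the RNA data, and the level of Acly RNA in each liver was not analysed here, so the genotype labels were not checked on the RNA. An isoform switch and a change of the whole gene cannot be separated in such counts. Transcripts were kept with edgeR's filterByExpr by group, which left 36041. A single quasi-likelihood model in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with TMM scaling and robust dispersion covered all 16 libraries with 1 coefficient per group and 12 residual degrees of freedom. It gave 5 comparisons: IR against sham in each genotype, KO against WT after each surgery, and the genotype by IR interaction, which is the KO response minus the WT response. Benjamini-Hochberg adjustment was applied within a comparison, with a threshold of 0.05. DESeq2 1.42.0 was run as an alternative. All adjusted p-values of transcripts come from edgeR unless DESeq2 is named. The labels do not say whether the 4 libraries of a group came from separate animals, so the p-values measure only the spread between these libraries. Library totals ranged from 37787856 to 44597703 estimated counts (37.79 to 44.6 M). Pairs of libraries within a group differed far beyond counting noise, so no library was counted as a duplicate.

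Named transcripts are, per comparison, the 2 that rose most and the 2 that fell most by fold among those past the threshold with a mean of at least 1 CPM and with no overlap between the 4 libraries of one group and the 4 of the other. The no-overlap condition was not used for the interaction. The rule had been written for 6 genes per direction and was reduced because no gene names were used. Where a group had no estimated counts, the fold is a lower bound computed against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with a 95% counting interval. Both are scaled by library totals and not by TMM. The TMM factors were higher in KO IR (1.075 to 1.2) than in the other groups (0.864 to 1.017). On that scale the folds of transcripts higher in KO IR would be smaller. These bounds cover counting error only. The counts are kallisto estimates per transcript, so reads assigned to another isoform are not covered by the bounds. Library totals, the number of transcripts of at least 1 TPM and the share of TPM in the top 100 transcripts were compared with two-sided exact permutation tests over 70 arrangements, 12 tests in all, with a smallest possible p of 0.0286.

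Overlap of peaks means at least 1 shared base, and shares carry 95% Wilson intervals that cover counting error only. Peak coordinates are mm10, with starts counted from 1. Genes were the 21887 coding genes with coordinates in the RefSeq annotation of GRCm38.p6, the assembly that mm10 names. The gene table had no strand, so a gene counts as having a peak when a peak lies within 1 kb of either of its ends, in place of the planned window around the transcription start. In all, 41 gene lists covering liver metabolism, stress and injury responses, chromatin enzymes and markers of liver cell types were set up, with 667 entries, of which 649 (97.3%) matched a coding gene. The 13 mitochondrially encoded genes matched none. Each list's number of genes with a peak was placed among 10000 random lists of the same size, as a description of that library. For FLAG peaks, the random lists were also matched on the number of acetylated genes. Genes named for a change between conditions are the 6 with the largest total signal among those that had both acetylation marks in 1 condition and neither in the other. Named FLAG peaks are the 8 with the largest total signal within 1 kb of a gene end; peaks inside a gene and farther from its ends were not ranked. Names of the form Gm plus digits, Rik clones and LOC names were left out of both. FLAG peaks on placed chromosomes were also shifted to 100 sets of random positions on the same chromosome, with chromosome lengths from GenomeInfoDb 1.38.1. With 1 library per antibody and condition there was no test of any difference between peak lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for peaks, and matplotlib 3.10.9 for figures.

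The groups, the tests, the gene lists, the rules for named transcripts and FLAG peaks and most alternatives were chosen before the data were examined. The gene-end window, the 6 genes per class, the thinning of all libraries to the smallest total, the merging of KO peaks, the lists matched on acetylation and the comparison of fold sizes between WT libraries 1 and 2 and WT libraries 3 and 4 were chosen afterwards. The alternatives were other scaling, DESeq2, no filter or a stricter filter on low counts (10 CPM in 4 libraries), a fit of the compared groups alone, a block for the library number, a minimum log2 fold change of 1, leaving out each library in turn, a larger minimum overlap, the upper part of each peak list by signal, lists of equal length and a window of 2 kb. The model was tested on simulated counts for the 36041 transcripts with 100 transcripts changed by 1 and 100 by 2 on the log2 scale per comparison. It recovered 19 and 54 for IR in WT, 16 and 52 for IR in KO, 22 and 50 for KO against WT after sham, 17 and 48 after IR, and 12 and 28 for the interaction, with 0 in the wrong direction. Unchanged transcripts called were 4, 2, 4, 3 and 1. The overlap code recovered 700 of 700 overlaps planted among 2000 simulated peaks.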

Results

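The study asked what ATP citrate lyase (ACLY), the enzyme that makes acetyl-CoA from citrate outside mitochondria, does in liver injured by a period without blood flow followed by its return. RNA was measured in 4 groups of 4 liver libraries, WT and hepatocyte Acly KO after sham or IR surgery, with 37.79 to 44.6 M estimated counts per library. KO IR libraries 1 to 3 had 37.79, 37.9 and 38.22 M and the other 13 libraries had 42.8 or more. H3K27ac, H3K9ac and FLAG-tagged ACLY were mapped in cultured primary hepatocytes, with 1 library per antibody and condition. At the Acly gene (chromosome 11, 100476352 to 100528000, mm10) all 6 acetylation lists held a peak, among them KO HR H3K27ac at 100515511 to 100530445. Such a peak can lie outside the deleted part of the gene and checks nothing about the deletion, and Acly RNA was not analysed here.

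**Figure D1:**
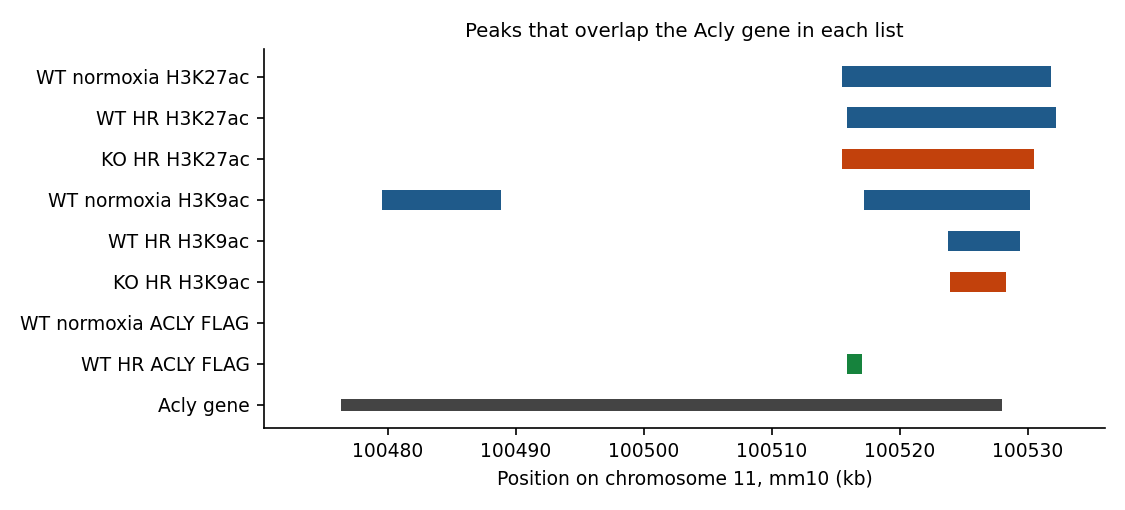
Peaks that overlap the Acly gene on chromosome 11 in each of the 8 lists (x axis, position in kb on mm10; bars span each peak; blue WT acetylation, orange KO acetylation, green FLAG; the grey bar is the gene). All 6 acetylation lists have a peak near 100528000, and the FLAG list of WT HR has a peak inside the gene at 100515871 to 100517060.

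The livers after IR separated from the sham livers, and the KO livers after IR lay farthest away. On the first principal component, which held 14.1% of the variance, the 8 sham libraries lay between -41.96 and -14.45, the WT IR libraries between -1 and 17.4 and the KO IR libraries between 41.1 and 75.12. KO IR livers had 18283 ± 922 transcripts of at least 1 TPM (SD, n = 4), against 16699 ± 520 in WT IR, 16080 ± 704 in KO sham and 16318 ± 339 in WT sham livers. The differences of KO IR from WT IR and from KO sham each had the smallest p the exact permutation test can give (p = 0.0286, n = 4, all 4 libraries above all 4), and neither passed adjustment over 12 tests (adjusted p = 0.1144, exact permutation test). The 100 most abundant transcripts held 65.77 ± 1.62% of TPM in KO IR, 69.94 ± 2.75% in WT IR and 71.04 ± 1.88% in KO sham livers (exact permutation p = 0.0571 and 0.0286, adjusted 0.1713 and 0.1144).

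**Figure D2:**
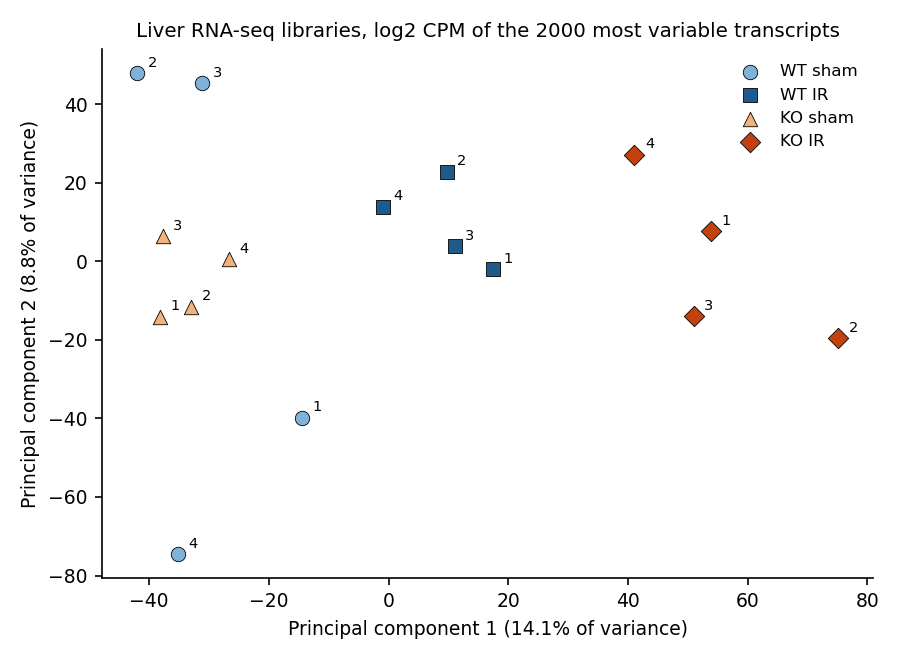
Each of the 16 liver libraries on the first and second principal components of log2 CPM over the 2000 most variable transcripts (axes in component units; symbols mark the 4 groups and numbers the libraries). KO IR libraries lie between 41.1 and 75.12 on the first component, beyond the highest WT IR library at 17.4.

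In WT liver, IR raised 513 transcripts and lowered 326 of the 36041 tested (edgeR, adjusted p under 0.05), 839 in all. The rise was largest in ENSMUST00000117082.1, with 801 estimated counts over the 4 IR libraries and 0 over the 4 sham libraries (at least 263-fold higher, 1.56 ± 0.455 TPM after IR, SD, n = 4, adjusted p = 0.0196 by edgeR). As estimates per transcript, such counts do not exclude a shift of reads between isoforms of a gene. ENSMUST00000107657.7 had 544 counts after IR and 0 after sham, at least 179-fold higher (adjusted p = 0.0166 by edgeR). The largest falls were in ENSMUST00000177567.7, from 13.5 ± 12.9 to 0.0129 ± 0.00598 TPM (SD, n = 4; 5644 and 5 counts, adjusted p = 0.00255 by edgeR), and ENSMUST00000090785.8, from 317 counts to 0, at least 107-fold lower. The median log2 fold change was 0.84 among the transcripts that rose and -0.84 among those that fell, and 406 of the rises and 258 of the falls were in transcripts of 3.6 CPM or more on average. DESeq2 called 1791, a fit without the KO libraries 264 and a fit without the filter on low counts 489, where the call of ENSMUST00000117082.1 was lost (adjusted p = 0.0559 by edgeR). With at least 10 CPM in 4 libraries 589 rose and 630 fell, so falls were then the more numerous. Without WT sham 2, WT IR 1, WT IR 2 or WT IR 3 the count was 512, 517, 424 or 456. The call of ENSMUST00000107657.7 was lost without KO sham 4, and that of ENSMUST00000090785.8 without WT IR 2 or WT IR 3.

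In KO liver, IR raised 2105 transcripts and lowered 1970, 4075 in all. ENSMUST00000127192.1 went from 1 count over the KO sham libraries to 1907 over the KO IR libraries (ratio 2110, 95% counting interval 377 to 83200), reaching 24.3 ± 8.93 TPM against 0.291 ± 0.479 TPM in WT IR livers (SD, n = 4, adjusted p = 0.000377 by edgeR for IR in KO). ENSMUST00000115342.9 rose from 0 to 638 counts, at least 235-fold by library totals. ENSMUST00000100933.9 fell from 810 counts to 0, at least 245-fold lower, and ENSMUST00000015107.12 from 405 to 0, at least 122-fold lower, while in WT livers they stood at 0.559 ± 0.33 and 0.721 ± 0.473 TPM after IR (SD, n = 4). The median log2 fold change was 0.98 among the rises and -0.9 among the falls. Among the shortest 20% of transcripts 262 rose and 420 fell, and among the longest 20% 469 rose and 251 fell. No alternative other than a minimum log2 fold change of 1 (1919 calls) moved this count by over 1.5 times. Falls were the more numerous without the low-count filter (1498 rose and 1549 fell). They were also the more numerous without KO sham 1 (1672 and 1717), KO sham 4 (1662 and 1739), KO IR 1 (1700 and 1728), KO IR 2 (1401 and 1460) or KO IR 3 (1885 and 1906).

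The responses of the genotypes, which share no libraries, overlapped. Of the transcripts that rose in WT, 352 also rose in KO (30 would be shared by independent lists), and of those that fell in WT, 260 also fell in KO (17.8 by independent lists). Of the 839 WT calls, 805 (95.9%) had the same direction in KO and 615 were called there with either direction. ENSMUST00000177567.7, the largest fall in WT, also went from 16.4 ± 10.5 to 0.14 ± 0.142 TPM in KO (SD, n = 4). ENSMUST00000107657.7 rose in KO as well, from 0.0029 ± 0.00395 to 2.18 ± 1.61 TPM (SD, n = 4, adjusted p = 0.00284 by edgeR). KO IR 4 did not share this rise, at 0.0121 TPM against 2.1 to 3.84 TPM in the other KO IR libraries. The other transcripts named for WT were not called in KO: ENSMUST00000117082.1 stood at 0.769 ± 0.29 TPM after sham and 0.525 ± 0.868 TPM after IR, and ENSMUST00000090785.8 at 0.216 ± 0.121 and 0.24 ± 0.224 TPM (SD, n = 4, adjusted p = 0.652 and 0.927 by edgeR). For these, the test of the difference between the genotypes' responses did not pass either (adjusted p = 0.0645 and 0.0916 by edgeR). The log2 fold change was larger in KO for 394 of the 839 (47%), a set selected on its size in WT. For the 500 transcripts with the smallest p in WT 1 and 2, the fold change was larger in KO than in WT 3 and 4 for 60.8%, and with these libraries exchanged for 53%. Across the 36041 transcripts, which are not independent replicates, the fold changes of the genotypes had a Pearson r of 0.198 and a Spearman rho of 0.289, and r was 0.67 with at least 10 CPM in 4 libraries and 0.071 with no filter.

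After sham surgery KO and WT livers differed in 3 transcripts. ENSMUST00000107389.7 was at 4.94 ± 3.2 TPM in WT and 0.318 ± 0.168 in KO (log2 fold change -3.95, SE 0.53, SD of TPM over n = 4, adjusted p = 0.0326 by edgeR), and ENSMUST00000165111.7 at 8.62 ± 4.26 and 1.19 ± 0.468 TPM (log2 fold change -2.87, SE 0.37, n = 4, adjusted p = 0.0326 by edgeR). The same direction held after IR, with 5.34 ± 0.947 against 0.65 ± 0.45 TPM for ENSMUST00000107389.7 and 9.9 ± 1.05 against 1.2 ± 0.325 TPM for ENSMUST00000165111.7 (SD, n = 4, edgeR adjusted p = 0.00287 and 0.000667). ENSMUST00000190336.6, which fails the minimum of 1 CPM and was named after its values were seen because the count is so low, had 0 counts in WT sham and 53 in KO sham livers, at least 17.5-fold higher. It was not particular to KO, at 0.142 ± 0.0345 TPM in WT IR, 0.194 ± 0.044 in KO sham and 0.18 ± 0.115 in KO IR livers (SD, n = 4). At an unadjusted p under 0.05, 1327 transcripts differed, against 1802 by chance, and DESeq2 called 55. Without the filter on low counts or without the IR libraries edgeR called 0, and it called 0 or 1 without any 1 of WT sham 2, KO sham 1, KO sham 2, KO sham 3, KO IR 1, KO IR 2 or each WT IR library. The calls of ENSMUST00000107389.7, ENSMUST00000165111.7 and ENSMUST00000190336.6 were lost on leaving out 12, 11 and 14 of the 16 libraries, with adjusted p up to 0.389, 0.56 and 1 over all alternatives by edgeR or DESeq2.

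After IR, KO livers had 799 transcripts above and 643 below WT livers, 1442 in all. ENSMUST00000032416.10 had 2830 counts over the KO IR libraries and 0 over the WT IR libraries, at least 1050-fold higher by library totals (11.9 ± 3.58 TPM in KO IR, SD, n = 4, adjusted p = 0.00775 by edgeR). ENSMUST00000189268.6 had 614 and 0 counts, at least 228-fold higher, but stood at 1.18 ± 1.19 TPM in WT sham and 1.19 ± 0.461 TPM in KO sham livers (SD, n = 4). The largest deficits in KO were ENSMUST00000100933.9 (0 against 426 counts, at least 128-fold lower) and ENSMUST00000015107.12 (0 against 397, at least 119-fold lower). The median log2 fold change was 1.05 among the transcripts above WT and -0.87 among those below. Among the shortest 20% of transcripts 93 were above and 108 below WT, and among the longest 20% 166 and 90. DESeq2 called 2908 and edgeR without the low-count filter 887, and with at least 10 CPM in 4 libraries 641 were above and 658 below WT. Without WT IR 2, WT IR 3, WT IR 4, KO IR 1 or KO IR 2 the count was 859, 885, 803, 915 or 626.

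**Figure D3:**
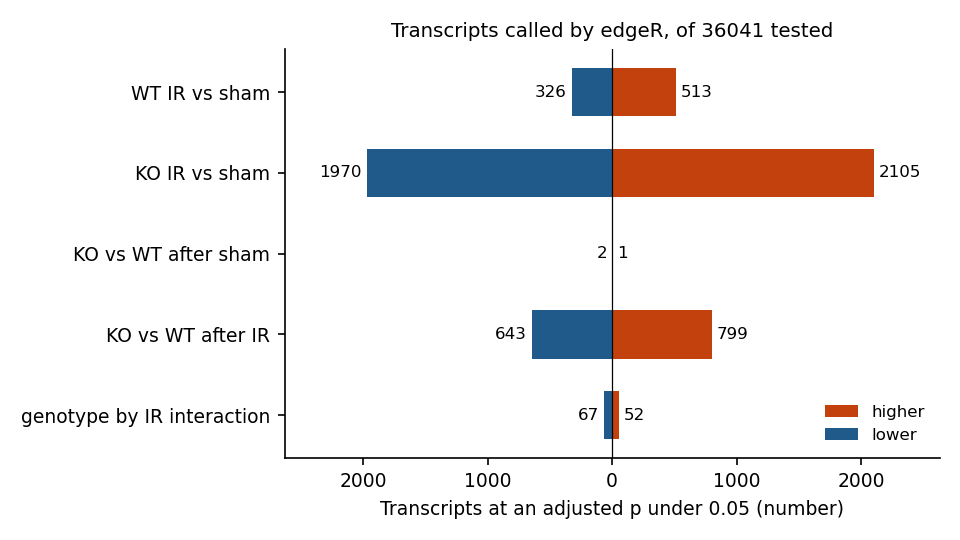
Number of transcripts that edgeR called at an adjusted p under 0.05 in each of the 5 comparisons (bars to the right, higher in the group named first; bars to the left, lower; for the interaction, a KO response above or below the WT response). The numbers are 513 and 326, 2105 and 1970, 1 and 2, 799 and 643, and 52 and 67.

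The response to IR itself differed between the genotypes in 119 transcripts, 52 with a higher and 67 with a lower fold change in KO. Of these, 76 moved in the same direction and further in KO, 4 in the same direction and less far, and 39 in opposite directions. ENSMUST00000109367.9 went from 0.369 ± 0.244 to 23.5 ± 7.61 TPM in KO and from 0.606 ± 0.374 to 1.3 ± 0.556 TPM in WT (SD, n = 4, log2 difference 4.54, SE 0.86, adjusted p = 0.0392 by edgeR). ENSMUST00000115099.8 went from 0.000895 ± 0.00075 to 0.654 ± 0.13 TPM in KO and from 0.458 ± 0.0912 to 0.252 ± 0.19 TPM in WT (SD, n = 4, adjusted p = 0.0331 by edgeR). ENSMUST00000100933.9 and ENSMUST00000015107.12, lost after IR in KO livers and not in WT livers, were the largest in the other direction (adjusted p = 0.0458 and 0.0384 by edgeR). These 4 calls were all lost without the low-count filter (adjusted p of 0.0529 to 0.0882 by edgeR). They were kept on leaving out only 3 of 16 libraries for ENSMUST00000109367.9 (WT sham 2, KO sham 4, KO IR 3) and ENSMUST00000115099.8 (WT IR 2, KO IR 3, KO IR 4), 2 for ENSMUST00000100933.9 (KO sham 4, KO IR 3) and 4 for ENSMUST00000015107.12 (WT sham 2, WT sham 4, KO sham 4, KO IR 3). DESeq2 called 1036, a filter of 10 CPM in 4 libraries 451 and no filter 67. Without KO IR 3, 148 had a higher and 254 a lower fold change in KO. Without WT sham 3, WT IR 1 to 4, KO sham 1 to 3, KO IR 1 or KO IR 2 it was 71, 60, 69, 65, 52, 65, 58, 53, 62 or 57. More were higher than lower in KO without WT sham 3 (39 and 32) and without WT IR 1 (31 and 29).

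In WT hepatocytes, H3K27ac stood at 18.82% of the 21887 coding genes in normoxia and 26.27% in HR, and H3K9ac at 29.63% and 34.04%. No list was tested for a gain beyond that of all genes. Immediate early genes, the first transcription factors induced by many stimuli, had H3K27ac at 10 of 17 members in normoxia and 13 in HR, with Fos, Egr1 and Atf3 added and H3K9ac present at all of these in both conditions. Heat shock genes went from 9 to 12 of 14 (Hspa1b, Dnajb1, Hspb1 and Chordc1 gained, Hsph1 lost), endoplasmic reticulum stress genes from 10 to 13 of 18 (Dnajb9, Calr, Chac1), and DNA repair genes from 1 of 22, Brca1, to 7 with Lig3, Lig4, Ogg1, Apex1, Fen1 and Atm, while their H3K9ac went from 12 to 10. Nuclear genes of the respiratory chain went from 7 to 11 of 18, with Sdha, Sdhb, Uqcrc2, Cox4i1 and Atp5a1 gained and Cyc1 lost. Among hypoxia targets H3K27ac stood at 10 of 18 in both conditions while H3K9ac went from 10 to 14, with Egln3, Ndrg1, P4ha1 and P4ha2 added. The H3K27ac count of the DNA repair list lay above 1.0% of random lists in normoxia and 65.4% in HR, that of immediate early genes above 100.0% in both, and that of the respiratory chain above 96.3% and 99.8%.

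In the other groups the H3K27ac counts of normoxia and HR differed by 3 members at most. The counts of immediate early, heat shock and endoplasmic reticulum stress genes also differed by 3, so those lists do not stand apart. Hepatocyte markers such as Alb, Apoa1 and Ttr had it at 12 of 15 genes in both. Cholesterol synthesis genes had it at 16 and 15 of 22, fatty acid synthesis genes at 12 and 11 of 18, bile acid genes at 10 and 10 of 13, acute phase genes at 13 and 12 of 22 and cytochrome P450 and related genes at 5 and 5 of 16. For genes of acetyl-CoA supply the counts were 6 and 9 of 12, with Pdha1, Dlat and Crat added. They were for glycolysis 7 and 9 of 16, for gluconeogenesis and the urea cycle 7 and 9 of 13, for NF-kB targets 6 and 9 of 15, for p53 targets 11 and 13 of 20, for NRF2 targets 13 and 14 of 18 and for ferroptosis genes 8 and 10 of 15. Histone acetylation enzymes had 4 and 7 of 20, with Crebbp, Kat7 and Kat8 added. Complement and coagulation genes had H3K27ac at 13 and 14 of 20, while H3K9ac went from 13 to 8, with Hc, F5, F11, Serpinc1 and Klkb1 lost. Cell cycle genes had H3K27ac at 2 and 2 of 25, growth factor genes at 5 and 5 of 17, matrix genes at 3 and 4 of 20, interferon genes at 2 and 4 of 16 and cytokine and chemokine genes at 2 and 3 of 18.

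The genes that had both marks in HR and neither in normoxia numbered 229, and 17 showed the reverse. By signal, the first 6 of the former were Lsm10, a component of the U7 particle that processes histone RNA, B4galt5, Gdf3, Dvl2, a Wnt pathway protein, Sema4g and Masp2, a protease of the lectin pathway of complement. The H3K27ac peak at Lsm10 spanned 126093681 to 126122160 on chromosome 4 and covered the gene at 126096562 to 126098584. The reverse group was led by Wfdc21, Nxt1, Apoc1, a lipoprotein gene, Dhcr7, which encodes an enzyme of cholesterol synthesis, Vapa and Tapt1. H3K27ac peaks numbered 5655 in normoxia and 8252 in HR with median widths of 10340 and 7410 bp, and H3K9ac peaks 6513 and 7593 with 7790 and 6400 bp. Of the HR peaks, 70.0% (95% interval 69.0 to 71.0) overlapped a normoxia peak for H3K27ac and 80.9% (80.0 to 81.7) for H3K9ac, and 96.0% and 92.0% of normoxia peaks overlapped an HR peak. The HR lists are longer, so more genes gain than lose a peak, and with 1 library per condition a gain can come from depth. The H3K27ac peaks of the 6 genes named for HR are among those of largest signal, of which 99.9% overlapped a normoxia peak. Such a gene can lie in or beside a region that had H3K27ac in normoxia, with only its 1 kb window newly reached. Of the normoxia H3K27ac peaks of largest signal, 99.9% overlapped an HR peak.

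**Figure D4:**
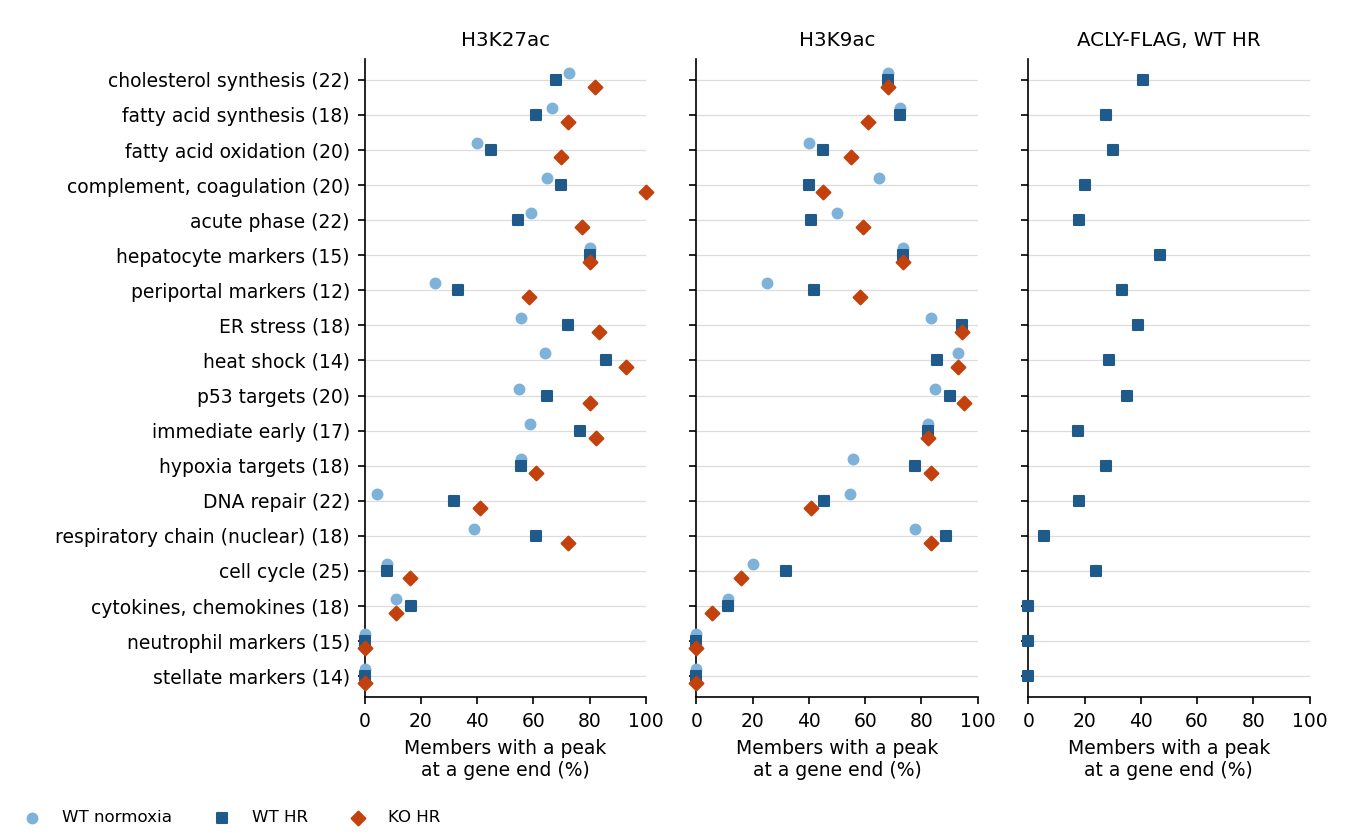
Percent of the members of 18 gene lists (number of members in parentheses) with a peak within 1 kb of a gene end, for H3K27ac, H3K9ac and FLAG-tagged ACLY (x axes, percent; circles WT normoxia, squares WT HR, diamonds KO HR; 1 library each, so no error). H3K27ac in KO HR reaches all 20 complement and coagulation genes, and neutrophil and stellate cell markers have no peak.

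KO hepatocytes in HR had H3K27ac at 32.91% of coding genes against 26.27% in WT HR, and H3K9ac at 32.6% against 34.04%. H3K27ac counts did not differ for hepatocyte markers (12 of 15), bile acid genes (10 of 13) and cytochrome P450 and related genes (5 of 16), and pericentral markers had 1 against 2 of 12. Complement and coagulation genes had it at 20 of 20 members against 14 in WT, with C4b, C9, F7, F9, F10 and Plg added. Fatty acid oxidation genes had it at 14 against 9 of 20 (Acadvl, Ehhadh, Fgf21 and Slc25a20 among those added) and acute phase genes at 17 against 12 of 22 (Saa4, Orm2, Orm3, Fgg, Itih4). Periportal hepatocyte markers had 7 against 4 of 12 (Ass1, Pigr, Arg1) and genes of apoptosis and related death pathways 8 against 4 of 17 (Casp8, Mlkl and Gsdmd among those added), the latter also at 4 in WT normoxia. Cholesterol synthesis genes had 18 against 15 of 22, fatty acid synthesis genes 13 against 11 of 18, p53 targets 16 against 13 of 20, histone acetylation enzymes 10 against 7 of 20, and acetyl-CoA supply genes 9 in both. For H3K9ac the counts went both ways, with complement and coagulation genes at 9 against 8, genes of death pathways at 7 against 8, fatty acid synthesis genes at 11 against 13 and cholesterol synthesis genes at 15 in both. This mark stood at 19 against 18 p53 targets, 10 against 12 histone acetylation enzymes and 9 against 10 acetyl-CoA supply genes. It was also found at more genes in KO for other lists, with periportal markers at 7 against 5, acute phase genes at 13 against 9 and fatty acid oxidation genes at 11 against 9. NF-kB targets had it at 6 against 9 of 15 (Nfkbie, Icam1 and Irf1 absent in KO; H3K27ac at 10 against 9). Cell cycle genes had it at 4 against 8 of 25 (Cdc20, Mcm2, Mcm5 and Rrm2 absent in KO; H3K27ac at 4 against 2).

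Of the genes with both marks in 1 genotype and neither in the other in HR, 221 had them in KO and 77 in WT. With every list cut to its peaks of larger signal the numbers were 236 and 121. Genes added by this cut had a peak of smaller signal in the other genotype. The KO group was led by Ugt1a1, which encodes the enzyme that conjugates bilirubin, and its neighbour Mroh2a, which share a peak on chromosome 1 at 88210606 to 88226351, followed by Cyren, Ppil6, Asrgl1 and Tmem125. The WT group was led by Slc17a5, a lysosomal sialic acid exporter, with a peak on chromosome 9 at 78502401 to 78536040, followed by Tns2, Cyb5r3, Vsig10, Nfic and Gp1ba. These WT peaks are among the H3K27ac peaks of largest signal in WT HR, of which 100.0% overlapped a KO HR peak. For them, only the 1 kb window at the gene end lacked H3K27ac in KO, and the regions did not. Of the KO H3K27ac peaks of largest signal, 99.8% overlapped a WT HR peak. KO H3K27ac peaks numbered 14418 with a median width of 3845 bp, against 8252 of 7410 bp in WT HR, and covered 81.05 against 87.5 Mb. KO H3K9ac peaks numbered 8837 of 2961 bp against 7593 of 6400 bp, covering 30.35 against 57.81 Mb. Of the KO peaks, 66.9% (95% interval 66.1 to 67.6) overlapped a WT HR peak for H3K27ac and 82.9% (82.1 to 83.6) for H3K9ac, and 98.0% and 88.9% of WT HR peaks overlapped a KO peak. The KO lists were made on another coordinate grid and there is 1 library per genotype, so genotype, depth and processing were not separated.

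FLAG-tagged ACLY gave 3666 peaks in WT HR and 1 in WT normoxia. The FLAG peaks of HR with the largest signal at a gene end lay at Slc25a47, a mitochondrial carrier of liver (chromosome 12, 108849591 to 108857200), Thrsp, a regulator of lipid synthesis (chromosome 7, 97412911 to 97419860), and Klf15, a transcription factor of the fasting response (chromosome 6, 90461241 to 90467590). They were followed by a peak shared by Gys1, Ftl1 and Bax, a peak shared by Zfp36 and Med29, and peaks at Bcl6, Pck1, the gene of the gluconeogenic enzyme PEPCK, and Irs2, which encodes an insulin receptor substrate. Of these 8 peaks, that at Pck1 (chromosome 2, 173152271 to 173157080) overlapped neither an H3K27ac nor an H3K9ac peak of WT HR. FLAG peaks stood at 9 of 22 cholesterol synthesis genes (Hmgcs1, Idi1, Fdps and Srebf2 among them), 7 of 15 hepatocyte markers, 7 of 18 endoplasmic reticulum stress genes, and 7 of 20 p53 targets. They stood at 6 of 20 fatty acid oxidation genes (Acadm, Acadl, Hadha, Hadhb, Ehhadh, Pdk4), 6 of 25 cell cycle genes, 5 of 18 fatty acid synthesis genes including Fasn, 3 of 12 acetyl-CoA supply genes (Slc25a1, Cs, Acat2) and 1 of 18 respiratory chain genes, Atp5b. Among random lists with as many acetylated genes, these counts exceeded 99.5% for cholesterol synthesis, 99.0% for hepatocyte markers, 92.6% for endoplasmic reticulum stress, 89.7% for p53 targets, 98.2% for fatty acid oxidation, 98.2% for cell cycle, 77.3% for fatty acid synthesis, 57.4% for acetyl-CoA supply and 1.0% for the respiratory chain, as a description of this library.

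FLAG and acetylation lay at the same genes more often than at other genes. Of 3666 FLAG peaks, 57.3% (95% interval 55.7 to 58.9) overlapped an H3K27ac or H3K9ac peak of WT HR, and for peaks on placed chromosomes the share was 58.0%, against 3.8% to 6.2% for shifted positions. Of the 2210 genes with a FLAG peak at an end, 1804 (81.6%) had an acetylation peak there, against 36.2% of all coding genes. FLAG stood at 22.77% of acetylated genes and 2.91% of the rest. Among the peaks of larger signal in each list the overlap was 47.1%. The single FLAG peak of normoxia lay on chromosome 9 at 2999971 to 3038540, with no coding gene, and its maximum was 251.6 times the largest maximum of the HR list. In HR the Acly gene carried a FLAG peak at 100515871 to 100517060.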

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

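The tests of 1 extreme region in the FLAG list, of KO peaks outside WT peaks, of the reverse split and of calls with an unadjusted p under 0.05 in WT were chosen only after the results were seen, as were thinning and merging of KO peaks.

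The response to IR differed between KO and WT livers in 119 transcripts by the interaction test of edgeR (adjusted p under 0.05), among them ENSMUST00000109367.9, which reached 23.5 ± 7.61 TPM in KO IR and 1.3 ± 0.556 TPM in WT IR livers (SD, n = 4). Only the real grouping, 1 of 30 regroupings of genotype within surgery, gave as many, and the highest other gave 6. A share of 1 in 30 is the smallest this test can give, so it argues against chance without excluding it. Regroupings mix libraries of groups that differ, which widens the fitted spread, so the gap from 119 to 6 adds nothing to that share. For IR against sham in WT, 1 of 35 splits of the libraries, the real one, gave as many calls as the real 264 of the fit on those libraries alone, and the highest other gave 2. In KO the real split gave 3751 and the highest other 1. For KO against WT after IR they gave 996 and 1, again with 1 of 35 splits reaching the real count. That is the smallest share 35 splits can give, so it argues against chance for these comparisons without excluding it. The same limit holds for the gap to the other splits. For KO against WT after sham that fit gave 0 calls by edgeR, beside 1327 transcripts at an unadjusted p under 0.05 and 55 calls by DESeq2 in all libraries. With 0 calls, 35 of 35 splits must give as many (the highest other gave 1), so the splits decide nothing there. ENSMUST00000107389.7 and ENSMUST00000165111.7, lower in KO after sham, were also called lower after IR, in other libraries (edgeR adjusted p = 0.00287 and 0.000667).

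Single libraries stood far from the other 3 of their group in 8 of 62 groups of values tested, and chance alone gives about 1 in 20. In 3 of the 8 the other libraries were all at 0, where any value above 0 stands out, so these show nothing beyond their values. KO IR 4 had 44.35 M counts, against 37.79 to 38.22 M in the other KO IR libraries. WT IR 4 had 15928 transcripts of at least 1 TPM, against 16895 to 17065. KO IR 2 had 1.82 TPM of ENSMUST00000117082.1, against at most 0.21. For ENSMUST00000127192.1, WT sham 1 had 0.396 TPM against 0 and WT IR 3 had 1 TPM against at most 0.164. ENSMUST00000032416.10 stood at 0.143 TPM in WT sham 1 and 0.56 TPM in KO sham 1, against 0 in the other libraries of each group. KO sham 1 had 1.88 TPM of ENSMUST00000189268.6, against 0.909 to 0.991.

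KO and WT livers differed in 1442 transcripts after IR, and ENSMUST00000032416.10 was at least 1050-fold higher in KO by library totals. The lower depth of KO IR 1 to 3 is argued against as the whole cause by 1414 calls after thinning every library to the smallest total, and a loss of long transcripts by a difference of 0.069 between the median log2 fold changes of the longest and shortest 20% of transcripts, although calls shifted with length, from 93 higher and 108 lower in KO among the shortest to 166 and 90 among the longest. If KO livers carried the WT response further and nothing else, nearly all calls would have its sign, were that sign measured without error. Of the transcripts called against WT IR 1 and 2, 60.7% (95% interval 55.0 to 66.1, counting error only) had the sign measured in WT IR 3 and 4. The reverse split gave 72.2% (68.4 to 75.7). The sign came from 2 WT IR libraries and the share that its noise would leave was not computed, so these shares alone do not decide. Among calls with an unadjusted p under 0.05 for that response, where the sign is better measured, the shares were 60.2% and 77.4%. For those calls the shares argue against a response only carried further as the whole cause. For the rest that explanation stays open. A trend with length in part of the calls stays open, as do genotype, handling and cell composition, which were not tested.

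FLAG-tagged ACLY had 3666 peaks in HR, at genes such as Slc25a47, Thrsp and Pck1, and 1 in normoxia. The normoxia region on chromosome 9 had a maximum 251.6 times the largest of the HR list and is absent from the other 7 lists. Such an extreme region may have raised the calling threshold, so the lack of other peaks in normoxia may not mean a lack of binding. The caller and the signal scale of each list are not given in the sources used here, so the ratio cannot decide this. In HR, 58.0% of the placed peaks overlapped acetylated chromatin, against at most 6.2% for shifted positions, as signal at open chromatin would give, and as ACLY bound at active genes would give too. The 1566 peaks (42.7%) outside both marks, with that at Pck1 among them, are not accounted for by acetylated chromatin alone. No IgG list was used here and there is 1 library per condition, so binding and background stay open.

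KO acetylation peaks in HR were more numerous and narrower than WT peaks, with 14418 against 8252 for H3K27ac, and included complement and coagulation genes such as C9, F9 and Plg. Merging KO peaks within 10 bp left 14418, so that test of the finer grid of the KO lists is void, and the grid cannot be told apart from genotype with 1 library each. Broken WT peaks are argued against as the whole cause, because KO peaks outside every WT peak came to 77.5% of the H3K27ac excess, and merging within 5000 bp left 11696 KO and 7482 WT peaks with median widths of 4068 and 7660 bp. Of those, 94.6% were among the KO peaks of smaller signal, which may point to a deeper or more permissive list. Genotype, depth and the authors' processing stay open.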

How the results depend on the processing

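The tests after thinning and after merging of KO peaks were chosen only after the data were seen. In 418 alternatives of the named transcripts 0 changed sign; the signs of other calls were not followed. With 10 CPM in 4 libraries the majority turned from rises (513 against 326) to falls (589 against 630) for IR in WT, and from 799 against 643 to 641 against 658 for KO against WT after IR. For IR in KO (2105 against 1970) falls led without the filter and without KO sham 1, KO sham 4 or KO IR 1 to 3, and for the interaction higher values led without WT sham 3 or WT IR 1. DESeq2 after sham called 28 higher and 27 lower, against 1 and 2. The named transcripts of IR in KO and of KO against WT after IR kept their calls in all 88 and 89 alternatives, those of IR in WT in 82 of 89, those after sham in 22 of 68 and those of the interaction in 25 of 84. In the order IR in WT, IR in KO, KO against WT after sham, after IR, and interaction, the 839, 4075, 3, 1442 and 119 calls became 1791, 5571, 55, 2908 and 1036 with DESeq2, 489, 3047, 0, 887 and 67 without a filter on low counts, and 351, 1919, 3, 682 and 88 with a minimum log2 fold change of 1, which by construction keeps fewer. The interaction gave 451 with 10 CPM in 4 libraries, where fewer transcripts are tested. Fits of the compared groups alone, with fewer libraries, gave 264 in WT and 0 after sham. Leaving out 1 library gave 424 (WT IR 2) to 1168 (WT sham 1), 2861 (KO IR 2) to 4485 (WT sham 1), 0 to 4, 626 (KO IR 2) to 1728 (WT sham 1) and 52 (WT IR 4) to 4.0e+02 (KO IR 3, 148 higher and 254 lower in KO), where 49 of the 52 were among the 119. Other scaling (812, 4058, 3, 1439 and 113) and thinning (780, 3980, 3, 1414 and 129) stayed within 1.5 times. Library numbers did not pair the samples: correlations of libraries of the same number ran from -0.066 to 0.042 and 2 of 16 libraries correlated best with their own number. With a replicate block on these numbers 595, 3618, 0, 1129 and 35 were called, the last with 19 higher and 16 lower in KO, against 52 and 67. Beside the counts of 0 by edgeR after sham stand 1327 transcripts at an unadjusted p under 0.05. Apart from fewer libraries or transcripts, the cause was not tested. The correlation of the genotypes' responses moved from 0.198 to 0.67 and its slope from 0.238 to 0.95 with 10 CPM in 4 libraries, and to 0.071 and 0.076 without a filter; the cause was not tested. For overlap shares in the order HR in normoxia, normoxia in HR, KO in WT HR and WT HR in KO, H3K27ac values moved to 68.2%, 93.8%, 65.4% and 96.7% among peaks of larger signal and to 88.2%, 84.4%, 91.9% and 82.7% with lists of equal length, and H3K9ac values to 76.1%, 87.3%, 77.5% and 85.2%, and 88.7%, 86.8%, 87.8% and 82.5%. Among peaks of larger signal both lists of a pair were cut, so a peak can lose its overlap because its partner was cut. Against the full lists, in the same order, the peaks of largest signal had shares of 99.9%, 99.9%, 99.8% and 100.0% for H3K27ac. For H3K9ac these shares were 99.7%, 99.6%, 99.8% and 99.7%. FLAG overlap with either mark moved to 47.1% with the FLAG and acetylation lists both cut to their peaks of larger signal. Among peaks of larger signal, genes with a peak fell by construction to 2365, 3402 and 4420 (H3K27ac in normoxia, HR and KO), 3676, 4313 and 4095 (H3K9ac) and 1219 (FLAG). Genes with both marks in WT and neither in KO rose from 77 to 121. Genes added to that group had a KO peak of smaller signal that was cut, so the rise too follows from the construction. Merging KO peaks and a larger minimum overlap left each overlap share within its interval. Length offsets, removal of mitochondrial genes and the gene-list tests on RNA were not run. At this depth the simulated model recovered 12 to 22 of 100 changes of 1 on the log2 scale, so many changes of that size were not detectable.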

Other observations

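The tests of FLAG counts matched on acetylation, the genes by a single mark and the list of FLAG peaks at any position were chosen only after the data were seen.

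The acetylation lists held peaks at few genes of cells other than hepatocytes. Of the marker lists, 15 neutrophil, 14 stellate cell, 7 mesothelial, 10 erythroid and platelet and 14 other-organ genes had no acetylation peak in any list. Kupffer cell markers had H3K27ac at 2 of 13 in each condition, Slc40a1, also in the ferroptosis list, and Id3. Monocyte and macrophage markers had it at 2, 2 and 3 of 15 in WT normoxia, WT HR and KO HR, cholangiocyte markers at 1, 1 and 2 of 11 (Sox9 added in KO), endothelial markers at 1 of 15 (Lyve1) and lymphocyte markers at 0, 0 and 1 of 16 (Cd79a). Periportal markers had H3K27ac at 3, 4 and 7 of 12 and pericentral markers at 2, 2 and 1 of 12. FLAG peaks stood at 4 of 12 periportal genes (Gls2, Hal, Pck1, Arg1), above 97.3% of random lists with as many acetylated genes, and at 0 of 12 pericentral genes. They stood at 5 of 15 ferroptosis genes (Tfrc, Ftl1, Ncoa4, Lpcat3, Chac1), above 92.9%, at 5 of 15 NF-kB targets, above 90.1%, and at 0 of 16 cytochrome P450 and related genes.

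Genes that differed in H3K27ac, whatever their H3K9ac, include by definition those that differed in both marks. In KO and not WT HR it stood at 1684 genes, led by Abcb4, the phospholipid exporter of bile, with a peak on chromosome 5 at 8892958 to 8905782, Cacnb4 and Prrt2, and in WT and not KO HR at 229 genes, led by Slc17a5, Rusc2 and Lenep. In WT HR and not normoxia it stood at 1806 genes, led by Fancc, a DNA crosslink repair gene, Rusc2 and Dhx38. In normoxia and not WT HR it stood at 177 genes, led by Mtss1, with a peak of 118820 bp. That peak ended at 59082980, inside the gene, which ends at 59083956, so it only just reached the 1 kb window. It does not show that the region lost the mark in HR. A similar limit holds for the other genes named here by H3K27ac. Of the WT HR peaks of largest signal, 99.9% overlapped a normoxia peak and 100.0% a KO HR peak. Of the KO HR peaks of largest signal, 99.8% overlapped a WT HR peak. Bcl2l1, which encodes an inhibitor of apoptosis, led the 993 genes with H3K9ac in WT HR and not KO HR, and Ugt1a1 the 677 in the other direction.

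Of the 10 FLAG peaks of HR with the largest signal at any position, 3 had no coding gene within 1 kb, on chromosomes 17, 1 and 5, and 4 lay on chromosome 4 between 145435291 and 147289540, inside Zfp978, Zfp993 and Gm42346 and over 1 kb from the ends of these genes. FLAG peaks on unplaced sequence numbered 48 of 3666 (1.309%), against 0.007% to 0.04% of the peaks in the acetylation lists. The fold changes of KO against WT after sham and after IR, which share no libraries, had a Pearson r of 0.009 across transcripts, which are not independent replicates.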
